A study of Mus musculus and Homo sapiens with 27 samples.

How the data were processed

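RNA sequencing libraries were made from 2 cell lines that stably expressed an enzyme the labels call ERM-located LAP, and the 27 libraries fall into 3 sets of 9 (HEK293T 3G, MC38 12G and MC38 3G), each with 3 libraries in each of 3 groups. Per the labels' protocols, RNA was extracted, treated with DNase, joined to biotin azide and captured on streptavidin beads, a part was kept before capture, and libraries were made with the NEBNext Ultra II RNA kit. Per the submitters' processing notes, the authors used cutadapt 1.18, HISAT2 2.1.0, HTSeq 0.7.2 and DESeq2 1.16.1 with the human build GRCh38 and the mouse build GRCm39. The deposited values are whole-number read counts per Ensembl gene, 1 table per set, with 57992 features for HEK293T and 56691 for each MC38 set. Strand, the handling of reads with several matches, and the annotation release used for counting are not given in the sources used here. Counts of genes with near-identical copies (Gapdh, ribosomal proteins, histones and Eef1a1 among them) and of small nucleolar RNAs inside host genes are therefore uncertain. No column was left unused, and the submitters' DESeq2 output was not used here.

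Mouse gene names came from the GENCODE M21 annotation, which named 52073 of the 56691 features. That annotation describes the older mouse build GRCm38, so it served for names, transcript lengths and protein sequences, and no coordinates are given. HEK293T features are reported by Ensembl ID, since the name table used here covered 0 of them, and gene lists were therefore tested in MC38 alone. The MC38 12G set was used as the main description of MC38, because in each of the 9 pairs of libraries with the same title 0 features had more counts in 3G than in 12G, and 3G totals were 67.8% to 68.9% of 12G totals. Between other replicates of a group, 2558 to 7472 features were higher in 3G. The dispersion of the counts around 1 shared proportion, treating the libraries of a pair as separate samples, was 0.270 to 0.427 for same-title pairs and 1.42 to 3.24 for other pairs. Around a random subset of the 12G counts at 1 shared proportion, the dispersion of same-title pairs was 1.46 to 2.18, where 1 would mark a plain random subset, so how the 3G counts were drawn stays unknown. Both MC38 sets were read as deeper and shallower counts of the same libraries, which leaves 18 distinct libraries. The labels do not say whether replicates were separate cultures, so the p-values measure the spread between these samples.

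Before the data were examined, the comparisons, the tests, the alternatives, the rule for naming genes and the 24 gene lists were fixed. For each set, all 9 libraries entered 1 fit with 1 coefficient per group: edgeR 4.0.16 in R 4.3.3, trimmed mean of M values (TMM) factors, the default low-count filter by group, and the 2-sided quasi-likelihood F test with Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. Levels are CPM (counts scaled to a common library size with TMM factors), given as mean ± SD with n = 3. Fold changes are on the log2 scale, given ± SE. This SE is the absolute log2 fold change divided by the square root of the F statistic. TMM factors set levels relative to the bulk of tested genes. Higher and lower therefore describe relative levels and not amounts of captured RNA. Genes called higher in Label_Enrich than in both other groups were counted, and that count was set beside 20 simulations with unchanged groups and beside the overlap of independent lists. Genes named by size were the 8 with the largest fold change in each direction among genes with a mean of at least 20 CPM, non-overlapping groups and a conventional symbol. To these were added 15 genes fixed by name, of which TUBB had no unambiguous mouse match, and up to 3 members of each list with the smallest p, with the most abundant member that did not pass. For HEK293T, whose features had no symbols here, that condition was dropped and 2 IDs in each direction were taken under the other conditions, in Label_Enrich against Label_Input alone, a change made once the IDs were seen to have no names. Genes outside this rule are said to be so. Some genes that the rule names are not reported here.

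The lists covered ER chaperones and folding enzymes; the translocon, signal peptidase and oligosaccharyltransferase; the ER membrane protein complex, ER shaping and ERAD; extracellular matrix; cell surface proteins; lysosomal proteins; Golgi and coat-vesicle cargo handling; ER-membrane sterol enzymes and the SREBP pathway; and cytosolic sterol enzymes. They also covered glycolysis, cytoskeleton, proteasome, cytosolic ribosomal proteins, the nuclear-encoded respiratory chain, mitochondrially encoded mRNAs, mitochondrial ribosomal proteins, long noncoding RNAs, structured small RNAs, replication-dependent histones, C2H2 zinc finger genes, immediate early genes, integrated stress and unfolded protein response targets, NRF2 targets and blood-lineage markers. Ribosomal, respiratory chain, histone and zinc finger genes were taken by the pattern of their symbols. Each list with more than 1 tested member was compared with all other tested genes by camera in limma 3.58.1, with a preset correlation of 0.01 between genes and adjustment over the lists of 1 comparison. The same test with a correlation estimated from the data and the rotation test fry were alternatives. Counts of called members are given over all genes tested and again adjusted over the list alone.

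The alternatives were RLE factors, the DESeq2 1.42.0 Wald test, no low-count filter, a stricter filter (1 CPM in 3 libraries and a mean count of 20), an adjusted p under 0.01, a minimum fold of 2, only the 6 libraries compared, a replicate block, removal of mitochondrially encoded genes, and each library left out in turn. Removal of features holding over 1% of any library was added after seeing the data. Each fit was tested on simulated counts with 200 changed genes. In HEK293T 3G, Label_Enrich against Label_Input, 66.0% of genes changed 2-fold and 21.0% of genes changed 1.5-fold were recovered, against 67.0% and 27.0% for Label_Enrich against NonLabel_Enrich. In MC38 12G these shares were 82.0% and 59.5% against Label_Input, and 90.0% and 69.5% against NonLabel_Enrich. In MC38 3G they were 82.0% and 58.5%, and 88.5% and 71.5%. False calls made up 2.19% to 6.90% of the simulated calls over these fits. A simulated list of 50 genes changed 1.25-fold was called in each set with 0 unchanged lists called. Genes were simulated independently of each other, so this 0 says nothing about lists whose genes vary together.

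For MC38, the longest annotated protein of each gene was sorted by Kyte-Doolittle hydropathy. The N-terminal class had a window of 11 residues averaging at least 2.0 within the first 40 residues, the internal class had a window of 19 residues averaging at least 1.6 elsewhere, and the remaining proteins of at least 50 residues had neither. Trends of fold change on transcript length and GC share were removed with a loess curve; for gene lists, this check was chosen after their results were seen. Tables and plots used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, Biopython 1.88 and matplotlib 3.10.9. Tests of a difference between HEK293T and MC38 were not run, since human IDs were not paired with names, and tests of a difference between MC38 12G and 3G were not run, since both hold the same libraries.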

Results

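Proximity labelling driven by bioluminescence was applied to RNA in 2 cell lines, and total RNA was sequenced. HEK293T, a human embryonic kidney line, and MC38, a mouse colon carcinoma line, stably carried an enzyme called LAP in the labels and placed at the ERM, read here as the membrane of the endoplasmic reticulum (ER). Labelled cells were given 10 mM of a compound abbreviated PA and 50 µM furimazine, a luciferase substrate, for 15 to 60 min. The 27 libraries form 3 sets, HEK293T 3G, MC38 12G and MC38 3G, with 9 libraries each; what 3G and 12G stand for is not given in the sources used here. Within a set, 3 libraries are Label_Enrich (RNA of labelled cells after capture on streptavidin beads), 3 are Label_Input (RNA of labelled cells kept before capture) and 3 are NonLabel_Enrich (captured RNA titled as not labelled, whose treatment the labels do not describe separately).

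Library totals ran from 442059 to 1135243 counts in HEK293T 3G, from 13127181 to 18614808 in MC38 12G and from 9024263 to 12781918 in MC38 3G. In MC38 12G 1 feature without a name in the reference, ENSMUSG00000119584, took 59.3% ± 0.686 (SD, n = 3) of the counts in Label_Enrich, 80.7% ± 0.158 in Label_Input and 64.7% ± 1.97 in NonLabel_Enrich, which left 2702728 to 7727524 counts per library for all other features. A second feature, Lars2, bears the name of the mitochondrial leucyl-tRNA synthetase gene. It took 8.99% ± 0.160 of the counts in Label_Enrich, 7.03% ± 0.185 in Label_Input and 9.01% ± 1.03 in NonLabel_Enrich. Which RNAs the reads counted under Lars2 and ENSMUSG00000119584 came from was not examined. On the TMM scale used for all other levels Lars2 was lower in Label_Enrich than in Label_Input, with a log2 fold change of -1.26 ± 0.04 (SE, edgeR adjusted p = 3.96e-39). Lars2 and ENSMUSG00000119584 were named after their values were seen. The most abundant HEK293T feature took 5.29% ± 0.181, 12.8% ± 0.650 and 7.22% ± 0.349 of the counts in the same order of groups. The MC38 3G libraries were read as shallower counts of the MC38 12G libraries, which leaves 18 distinct libraries.

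The comparison of Label_Enrich with Label_Input asks which RNAs the whole procedure of labelling and capture enriched. In MC38 12G, mRNAs of secreted matrix and cell surface proteins were higher in Label_Enrich. Col4a1, a basement membrane collagen chain, stood at 78.3 ± 0.870 CPM in Label_Enrich and 28.8 ± 1.36 CPM in Label_Input (SD, n = 3), a log2 fold change of 1.44 ± 0.06 (SE, edgeR adjusted p = 3.49e-29). Other collagens followed: Col18a1 at 1.38 ± 0.09, Col5a2 at 1.28 ± 0.07 and Col4a2 at 1.26 ± 0.06, all on the log2 scale. Col6a3 rose from 246 ± 5.64 to 558 ± 6.57 CPM. Lamb1, a laminin chain, rose by 1.19 ± 0.06, and the receptor-type kinase genes Ephb4 and Ptk7 by 1.21 ± 0.08 and 1.20 ± 0.08. At the other end, Rnu12, the U12 spliceosomal RNA, had a log2 fold change of -3.91 ± 0.09. The Y RNA genes Rny1 and Rny3 were at -3.89 ± 0.06 and -2.84 ± 0.06, and the small nucleolar RNAs Snord17 and Snord15a at -3.85 ± 0.10 and -2.93 ± 0.09. The mitochondrial ribosomal RNA mt-Rnr2 stood at 1664 ± 67.4 CPM against 15116 ± 62.4 CPM (-3.18 ± 0.04), and mt-Rnr1 at 1436 against 11516 CPM.

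Of 27 tested extracellular matrix genes, 23 were called higher and 0 lower in Label_Enrich (24 and 0 adjusted over the list alone), with a median log2 fold change of 0.99 and a camera adjusted p of 2.68e-20. Col3a1 rose by 1.03 ± 0.04 and Col6a1 by 1.06 ± 0.05, while Thbs1 had 0.17 ± 0.10 (edgeR adjusted p = 0.207). Among 36 cell surface genes, 28 were higher and 1 lower, and 30 and 1 adjusted over the list alone. The median was 0.54 (camera adjusted p = 6.83e-15). Plxnb2 was at 1.04 ± 0.05 and Itgb1 at 0.83 ± 0.05. Igf2r rose from 61.8 to 138.5 CPM. The 23 ER chaperone and folding genes had 16 higher and 0 lower, and 17 and 0 adjusted over the list alone. The median was 0.52 (camera adjusted p = 2.35e-10). Hyou1 rose by 1.09 ± 0.06, Hspa5 (BiP) by 0.66 ± 0.04, Canx by 0.65 ± 0.04, Calr by 0.56 ± 0.04 and Hsp90b1 by 0.53 ± 0.05. For 23 lysosomal genes, whose products are made at the ER, 15 were higher and 0 lower, and 16 and 0 adjusted over the list alone. The median was 0.30 (camera adjusted p = 2.56e-06). Psap was at 0.61 ± 0.05 and Ctsl at 0.49 ± 0.04, with Lamp1 at -0.06 ± 0.05 (edgeR adjusted p = 0.336). Golgi and coat-vesicle genes had 13 of 21 higher and 2 lower, and 13 and 2 adjusted over the list alone. The median was 0.34 (camera adjusted p = 0.000133). Glg1 was at 0.77 ± 0.05 and Golim4 at 0.76 ± 0.08.

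Lists of ER membrane machinery were mixed in this comparison. The translocon, signal peptidase and oligosaccharyltransferase list had 12 of 26 higher and 7 lower, and 13 and 7 adjusted over the list alone. The median was 0.14 (camera adjusted p = 0.0366, adjusted p = 0.128 with an estimated correlation). Rpn1 was at 0.60 ± 0.06, Stt3a at 0.53 ± 0.06 and Sec61a1 at 0.38 ± 0.06. The ER membrane protein complex, shaping and ERAD list had 9 of 24 higher and 1 lower, the same numbers adjusted over the list alone (median 0.05, camera adjusted p = 0.0144, adjusted p = 0.0917 with an estimated correlation). Emc1 was at 0.94 ± 0.07 and Ckap4 at 0.69 ± 0.06. ER-membrane sterol enzymes and SREBP genes had 10 of 19 higher and 3 lower, again equal when adjusted over the list alone (median 0.24, camera adjusted p = 0.0184, adjusted p = 0.0813 with an estimated correlation). Srebf2, a sterol-regulated transcription factor held in the ER membrane, was at 0.77 ± 0.05. Of 7 cytosolic sterol enzymes 0 were higher and 2 lower, the same adjusted over the list alone (median -0.08, camera adjusted p = 0.576). Idi1 had -0.37 ± 0.10, and Fdps -0.50 ± 0.15, a call lost without the low-count filter or without Label_Input replicate 3 (adjusted p from 0.00547 to 0.117 over the alternatives).

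Cytosolic ribosomal protein mRNAs were lower as a group: 75 of 79 were lower and 1 higher (the same adjusted over the list alone; median -0.64, camera adjusted p = 3.08e-36). Rplp1 was at -1.15 ± 0.05 and Rplp0 at -0.68 ± 0.04. The nuclear-encoded respiratory chain had 39 of 54 lower and 0 higher, and 42 and 2 adjusted over the list alone. The median was -0.49 (camera adjusted p = 2.42e-11). Cox7c was at -0.92 ± 0.11 and Cox8a at -0.68 ± 0.08. Mitochondrial ribosomal proteins had 33 of 77 lower and 0 higher, and 37 and 0 adjusted over the list alone. The median was -0.35 (camera adjusted p = 4.35e-08). Replication-dependent histones had 44 of 57 lower and 0 higher, and 48 and 0 adjusted over the list alone. The median was -0.73 (camera adjusted p = 1.59e-20, adjusted p = 0.0506 with an estimated correlation). Transcripts of these genes were short, with median lengths of 1106 nt for cytosolic ribosomal, 977 nt for respiratory chain and 572 nt for histone genes, and after removal of the trend of fold change on length their medians were -0.33, -0.12 and -0.29. All 8 tested mRNAs encoded in mitochondrial DNA were lower, also adjusted over the list alone (median -1.63, camera adjusted p = 1.73e-10, adjusted p = 0.0506 with an estimated correlation), with mt-Nd1 at -1.90 ± 0.05 and mt-Co1 at -1.41 ± 0.05.

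Immediate early genes, which encode short-lived mRNAs of the first response to stimuli, had 19 of 23 lower and 1 higher, and 21 and 1 adjusted over the list alone. The median was -0.86 (camera adjusted p = 1.87e-13). Egr1 stood at 69.0 ± 1.54 CPM in Label_Enrich and 138 ± 5.76 CPM in Label_Input. Ier2 was at -1.02 ± 0.06, and Dusp1 at 34.1 against 68.3 CPM. Integrated stress and unfolded protein response targets had 8 of 16 lower and 2 higher, and 8 and 3 adjusted over the list alone. The median was -0.23 (camera adjusted p = 0.0208, adjusted p = 0.0813 with an estimated correlation). Chac1 was at -0.77 ± 0.08 and Atf4 at -0.45 ± 0.05. NRF2 targets had 8 of 11 lower and 0 higher, and 9 and 0 adjusted over the list alone. The median was -0.43 (camera adjusted p = 0.000250, adjusted p = 0.0506 with an estimated correlation). Hmox1 was at -1.15 ± 0.07 and Fth1, a ferritin chain, at -0.60 ± 0.04. The cytoskeleton list had 13 of 18 lower and 3 higher, equal when adjusted over the list alone (median -0.29, camera adjusted p = 0.01001, adjusted p = 0.126 with an estimated correlation): Actb had -0.49 ± 0.04, whereas Flna and Myh9 rose by 0.73 ± 0.04 and 0.68 ± 0.04. Long noncoding RNAs had 8 of 13 lower and 1 higher, and 9 and 1 adjusted over the list alone. The median was -0.42 (camera adjusted p = 0.00566, adjusted p = 0.0700 with an estimated correlation). Snhg1 was at -0.75 ± 0.10 and the nuclear RNA Malat1 at 0.61 ± 0.04.

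Glycolysis genes went both ways, 3 of 12 higher and 4 lower, and 4 and 5 adjusted over the list alone. The median was -0.03 (camera adjusted p = 0.643). Gapdh was at -0.99 ± 0.08, Aldoa at -0.45 ± 0.04 and Pkm at 0.34 ± 0.04. Of 31 proteasome genes 2 were higher and 7 lower, the same adjusted over the list alone (median -0.06, camera adjusted p = 0.106). Psmb3 was at -0.55 ± 0.07. C2H2 zinc finger genes had 11 of 282 higher and 15 lower (4 and 8 adjusted over the list alone); their median was -0.03 while camera pointed upward (adjusted p = 0.963). Scarna2 was the sole tested member of the structured small RNA list and had -1.66 ± 0.06 (edgeR adjusted p = 1.03e-34). Small RNAs named above, such as Rnu12 and Rny1, are not on that list. Cd68 was the sole tested member of the blood-lineage list, at 1.62 ± 0.232 CPM against 2.37 ± 0.331 CPM and -0.56 ± 0.27 (edgeR adjusted p = 0.109). Eef1a1, a cytosolic translation factor, had -0.05 ± 0.04 (edgeR adjusted p = 0.351).

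In total, the edgeR quasi-likelihood test called 3354 of 11676 genes in MC38 12G at an adjusted p under 0.05, 1654 higher and 1700 lower in Label_Enrich than in Label_Input, of which 74 and 287 differed at least 2-fold. Groups did not overlap in 39.6% of tested genes, where chance gives 10%. Without the low-count filter the split was 2228 higher and 1177 lower, and the median change of a gene's log2 fold change, over genes tested both with and without the filter, was 0.10. The medians of the glycolysis, proteasome, cytosolic sterol and zinc finger lists changed sign there. The plot of library values shows the spread between replicates for a selection of genes.

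**Figure D1:**
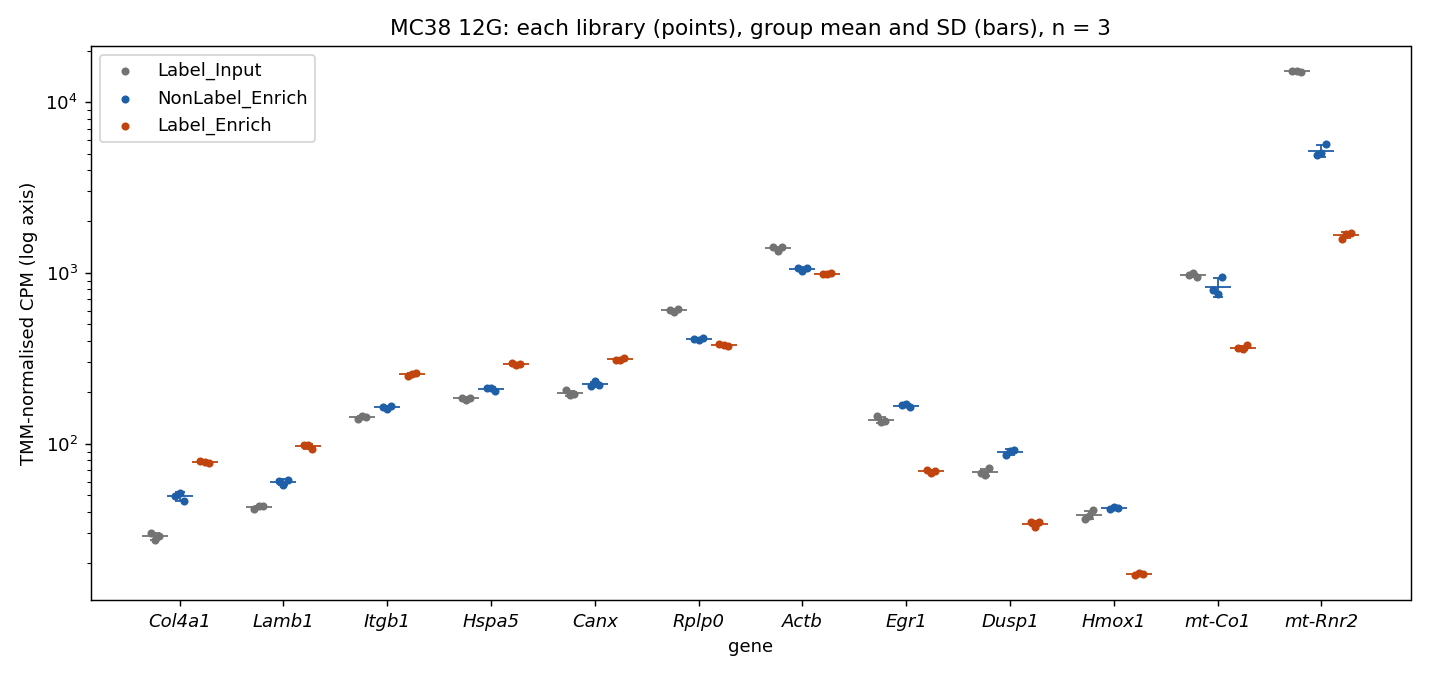
TMM-normalised CPM (log axis) of 12 genes in each MC38 12G library, with 1 point per library and bars for group mean and SD (n = 3). Lamb1 averaged 96.5 CPM in Label_Enrich, 42.5 in Label_Input and 59.5 in NonLabel_Enrich.

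The comparison of Label_Enrich with NonLabel_Enrich asks which RNAs were relatively higher or lower in captured RNA with labelling than without it. No RNA of unlabelled cells before capture was among the libraries, so in both comparisons with NonLabel_Enrich an effect of the labelling on the cells' own RNA levels was not separated from capture. In MC38 12G, Mogs, which trims glucose from new glycoproteins in the ER, rose from 15.7 ± 1.20 to 27.8 ± 1.28 CPM (SD, n = 3; log2 fold change 0.83 ± 0.07 SE, edgeR adjusted p = 7.88e-16). Collagens were again among the genes with the largest rises, Col5a2 at 0.80 ± 0.06, Col3a1 at 0.71 ± 0.04, Col4a1 at 0.67 ± 0.05 and Col1a2 at 0.65 ± 0.07, together with Lamb1 at 0.70 ± 0.05, the membrane protein gene Tm9sf3 at 0.66 ± 0.05 and Cdkn2c, a cell cycle inhibitor of the cytosol and nucleus, at 0.81 ± 0.07. Lower in Label_Enrich were mt-Rnr2 at -1.64 ± 0.04 and a run of stimulus and stress genes: Dusp1 at -1.39 ± 0.05, Ier2 at -1.36 ± 0.06, Hmox1 at -1.28 ± 0.06, Egr1 at -1.28 ± 0.05, Nr4a1 at -1.26 ± 0.06, Chac1 at -1.20 ± 0.06 and Trib1 at -1.19 ± 0.07. Egr1 stood at 69.0 ± 1.54 CPM in Label_Enrich and 167 ± 3.48 CPM in NonLabel_Enrich.

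The ER and secretory lists moved together against this reference. ER chaperones had 20 of 23 higher and 0 lower, and 22 and 0 adjusted over the list alone. The median was 0.42 (camera adjusted p = 5.79e-17). Pdia6 was at 0.62 ± 0.05, Hsp90b1 at 0.61 ± 0.05, Hspa5 and Canx at 0.48 ± 0.04 each and Calr at 0.34 ± 0.04. The translocon, signal peptidase and oligosaccharyltransferase list had 21 of 26 higher and 0 lower, the same adjusted over the list alone (median 0.34, camera adjusted p = 1.82e-13). Stt3a was at 0.56 ± 0.05, Ddost at 0.53 ± 0.05, Rpn1 at 0.52 ± 0.05 and Sec61a1 at 0.31 ± 0.05. The ER membrane protein complex, shaping and ERAD list had 12 of 24 higher and 0 lower, and 14 and 1 adjusted over the list alone. The median was 0.23 (camera adjusted p = 1.47e-05). Emc1 was at 0.43 ± 0.06. Extracellular matrix had 22 of 27 higher and 1 lower, and 23 and 1 adjusted over the list alone. The median was 0.50 (camera adjusted p = 6.93e-17). Cell surface proteins had 27 of 36 higher and 0 lower, and 28 and 1 adjusted over the list alone. The median was 0.29 (camera adjusted p = 3.58e-15). Itgb1 was at 0.63 ± 0.04. Lysosomal proteins had 20 of 23 higher and 0 lower, and 21 and 0 adjusted over the list alone. The median was 0.34 (camera adjusted p = 8.18e-15), with the proteases Lgmn and Ctsl at 0.60 ± 0.06 and 0.58 ± 0.04. Golgi genes had 12 of 21 higher and 0 lower, and 14 and 0 adjusted over the list alone. The median was 0.25 (camera adjusted p = 3.61e-07), and Lman1, a cargo receptor, rose by 0.42 ± 0.06. ER-membrane sterol enzymes and SREBP genes had 9 of 19 higher and 1 lower, and 10 and 1 adjusted over the list alone. The median was 0.14 (camera adjusted p = 0.00605, adjusted p = 0.0611 with an estimated correlation). Srebf1 was at 0.49 ± 0.06.

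Immediate early genes were lower in 22 of 23 cases and higher in 0, also adjusted over the list alone (median -1.19, camera adjusted p = 4.88e-33), the exception being Ccn2 at -0.38 ± 0.25 (edgeR adjusted p = 0.319). Integrated stress and unfolded protein response targets had 6 of 16 lower and 2 higher, and 7 and 2 adjusted over the list alone. The median was -0.15 (camera adjusted p = 0.00353). Sesn2 was at -0.78 ± 0.11 and Ppp1r15a at -0.72 ± 0.07. NRF2 targets had 5 of 11 lower and 1 higher, the same adjusted over the list alone (median -0.11, camera adjusted p = 0.0133, adjusted p = 0.123 with an estimated correlation): Srxn1 had -0.47 ± 0.07 and Prdx1 0.29 ± 0.05. Of 8 mitochondrially encoded mRNAs 7 were lower and 0 higher, also adjusted over the list alone (median -0.87, camera adjusted p = 1.11e-12), with mt-Co1 at -1.18 ± 0.05 and mt-Nd1 at -1.11 ± 0.05. Zinc finger genes had 6 of 282 higher and 25 lower (2 and 21 adjusted over the list alone); the median was 0.01, or -0.03 with the strict low-count filter, while camera pointed downward (adjusted p = 0.654). The list takes genes by symbol and not by the type of zinc finger. Its member with the smallest p was Zfp36 at -1.33 ± 0.08, which is also on the immediate early list.

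Several lists with medians below 0 against Label_Input had medians above 0 here. Histones had 31 of 57 higher and 0 lower, and 36 and 0 adjusted over the list alone. The median was 0.27 (camera adjusted p = 4.51e-12, adjusted p = 0.120 with an estimated correlation). Hist2h2ac was at 1.02 ± 0.08. Cytosolic ribosomal proteins had 36 of 79 higher and 2 lower, and 49 and 2 adjusted over the list alone. The median was 0.13 (camera adjusted p = 2.71e-08, adjusted p = 0.122 with an estimated correlation). Rps25 was at 0.39 ± 0.06. After removal of the length trend the ribosomal median was 0.08. The respiratory chain had 11 of 54 higher and 0 lower, the same adjusted over the list alone (median 0.14, camera adjusted p = 2.49e-05, adjusted p = 0.0648 with an estimated correlation). Cox7b was at 0.54 ± 0.09, and the list's length-corrected median was 0.09. Proteasome genes had 15 of 31 higher and 0 lower, and 18 and 0 adjusted over the list alone. The median was 0.17 (camera adjusted p = 1.69e-05). Psma2 was at 0.34 ± 0.07. Mitochondrial ribosomal proteins had 3 of 77 higher and 1 lower, and 0 and 0 adjusted over the list alone. The median was 0.06 (camera adjusted p = 0.125). Glycolysis had 2 of 12 higher and 1 lower, the same adjusted over the list alone (median 0.01, camera adjusted p = 0.534). Cytosolic sterol enzymes had 0 of 7 higher and 2 lower, and 0 and 3 adjusted over the list alone. The median was -0.13 (camera adjusted p = 0.0608). The cytoskeleton list had 3 of 18 higher and 6 lower, and 3 and 8 adjusted over the list alone. The median was -0.07 (camera adjusted p = 0.0877). Actg1 was at -0.23 ± 0.04 and Actb at -0.10 ± 0.04 (edgeR adjusted p = 0.0564). Long noncoding RNAs had 3 of 13 higher and 4 lower, the same over the list alone (median -0.02, camera adjusted p = 0.696). Malat1 was at 0.27 ± 0.04 and Neat1 at -0.50 ± 0.05; Scarna2 had -0.60 ± 0.06, and Cd68 -0.39 ± 0.22 (edgeR adjusted p = 0.227).

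Against NonLabel_Enrich, edgeR called 2342 of 11676 genes in MC38 12G, 1218 higher and 1124 lower, of which 15 and 96 differed at least 2-fold, and groups did not overlap in 34.6% of tested genes against 10% by chance. The DESeq2 Wald test called 1512, and without the low-count filter the split was 1297 higher and 760 lower. Eef1a1 had 0.20 ± 0.04 (edgeR adjusted p = 2.41e-05). Gapdh had -0.24 ± 0.07 (edgeR adjusted p = 0.0110, from 0.000327 to 0.127 over the alternatives), a call lost with DESeq2, without the low-count filter and without NonLabel_Enrich replicate 1 or 3. Rplp0 had -0.11 ± 0.04 (edgeR adjusted p = 0.0427, from 0.00971 to 0.299 over the alternatives), a call lost without the filter, with a replicate block, and when any 1 of the 6 libraries was left out.

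**Figure D2:**
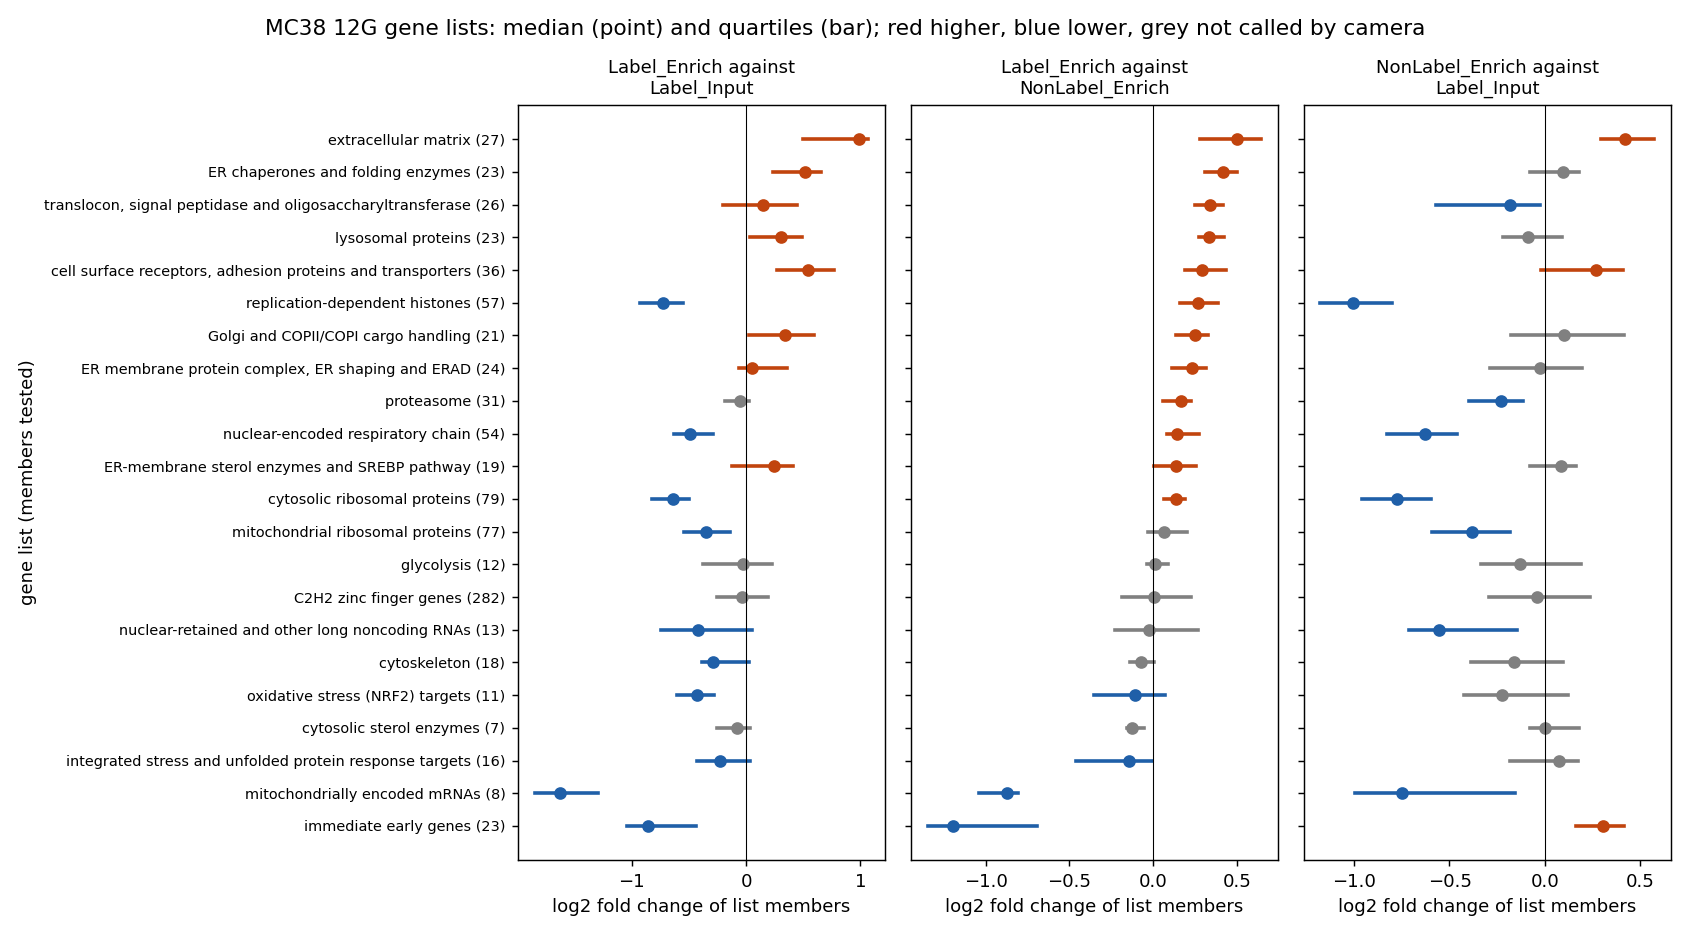
Median (point) and quartiles (bar) of the log2 fold changes of each gene list's tested members in MC38 12G, for the 3 comparisons; red lists were called higher, blue lower and grey not called by camera. The extracellular matrix median was 0.99 against Label_Input and 0.50 against NonLabel_Enrich, and the immediate early gene median was -0.86 and -1.19.

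NonLabel_Enrich against Label_Input sets captured RNA titled as not labelled against uncaptured RNA of labelled cells. Capture and an effect of labelling on the cells were thus not separated, and background below means only NonLabel_Enrich relative to Label_Input. In MC38 12G, Rny1 had a log2 fold change of -3.15 ± 0.06 (SE, edgeR adjusted p = 1.22e-51), mt-Rnr1 of -1.82 ± 0.04 and Rplp1 of -1.14 ± 0.05. These RNAs were thus lower in both captured groups than in Label_Input. Extracellular matrix genes were also higher in this background, 22 of 27 with 1 lower, the same adjusted over the list alone (median 0.42, camera adjusted p = 2.80e-10). Cell surface genes had 21 of 36 higher and 5 lower, and 22 and 5 adjusted over the list alone. The median was 0.27 (camera adjusted p = 0.000102), and 0.14 after removal of the length trend. Immediate early genes had 16 of 23 higher and 0 lower, and 16 and 1 adjusted over the list alone. The median was 0.31 (camera adjusted p = 9.14e-06). Col4a1 rose by 0.77 ± 0.07, Myc by 0.50 ± 0.07 and Jun by 0.56 ± 0.05. ER chaperones had 7 of 23 higher and 4 lower, and 8 and 5 adjusted over the list alone. The median was 0.10 (camera adjusted p = 0.317).

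Lower in this background were cytosolic ribosomal proteins (76 of 79 lower, 1 higher; 77 and 1 adjusted over the list alone; median -0.78, camera adjusted p = 4.13e-42), histones (51 of 57 lower, 0 higher; 53 and 0 adjusted over the list alone; median -1.01, camera adjusted p = 1.90e-29) and the respiratory chain (46 of 54 lower, 0 higher; 49 and 0 adjusted over the list alone; median -0.63, camera adjusted p = 1.78e-16). With the length trend removed, these 3 medians were -0.43, -0.46 and -0.22. Mitochondrial ribosomal proteins had 36 of 77 lower and 0 higher, and 42 and 0 adjusted over the list alone. The median was -0.38 (camera adjusted p = 5.64e-10). Proteasome genes had 19 of 31 lower and 1 higher, and 21 and 1 adjusted over the list alone. The median was -0.23 (camera adjusted p = 2.27e-05). The translocon list had 11 of 26 lower and 1 higher, and 12 and 1 adjusted over the list alone. The median was -0.18 (camera adjusted p = 0.00171, adjusted p = 0.0621 with an estimated correlation). Sec61g was at -1.09. Mitochondrially encoded mRNAs had 6 of 8 lower and 1 higher, the same adjusted over the list alone (median -0.75, camera adjusted p = 0.00171, adjusted p = 0.354 with an estimated correlation). Their median was -0.41 with the length trend removed and -0.43 with the GC trend removed. Long noncoding RNAs had 7 of 13 lower and 3 higher, and 8 and 3 adjusted over the list alone. The median was -0.55 (camera adjusted p = 0.0194, adjusted p = 0.138 with an estimated correlation). Col4a1, Jun, Myc, Rny1, mt-Rnr1, Rplp1 and Sec61g were named here after their values were seen. The other lists did not pass in this comparison. edgeR called 3440 of 11676 genes, 1727 higher and 1713 lower, with 48 and 279 differing at least 2-fold; without the low-count filter the split was 2047 and 1237.

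Genes above both references in MC38 12G numbered 596, Col4a1, Lamb1, Itgb1, Hspa5 and Canx among them, and 342 genes were below both. Opposite calls were made for 236 genes, 102 of them higher than in Label_Input and lower than in NonLabel_Enrich. Independent lists of these sizes would share 172.5 higher and 163.6 lower genes. The 20 simulations with unchanged groups gave 0 genes higher in both. They called 0.15 genes on average against Label_Input, so that 0 is no yardstick for the 596. The covariance of the 2 fold changes was 0.0655, against 0.0131 simulated with unchanged groups. Both comparisons share the 3 Label_Enrich libraries, which were not split between them, so part of the excess may come from that sharing. At least 2-fold above both references lay 1 gene, the pseudogene Atp5k-ps2, named after its values were seen, at 1.00 CPM in Label_Enrich, 0.434 in Label_Input and 0.300 in NonLabel_Enrich.

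**Figure D3:**
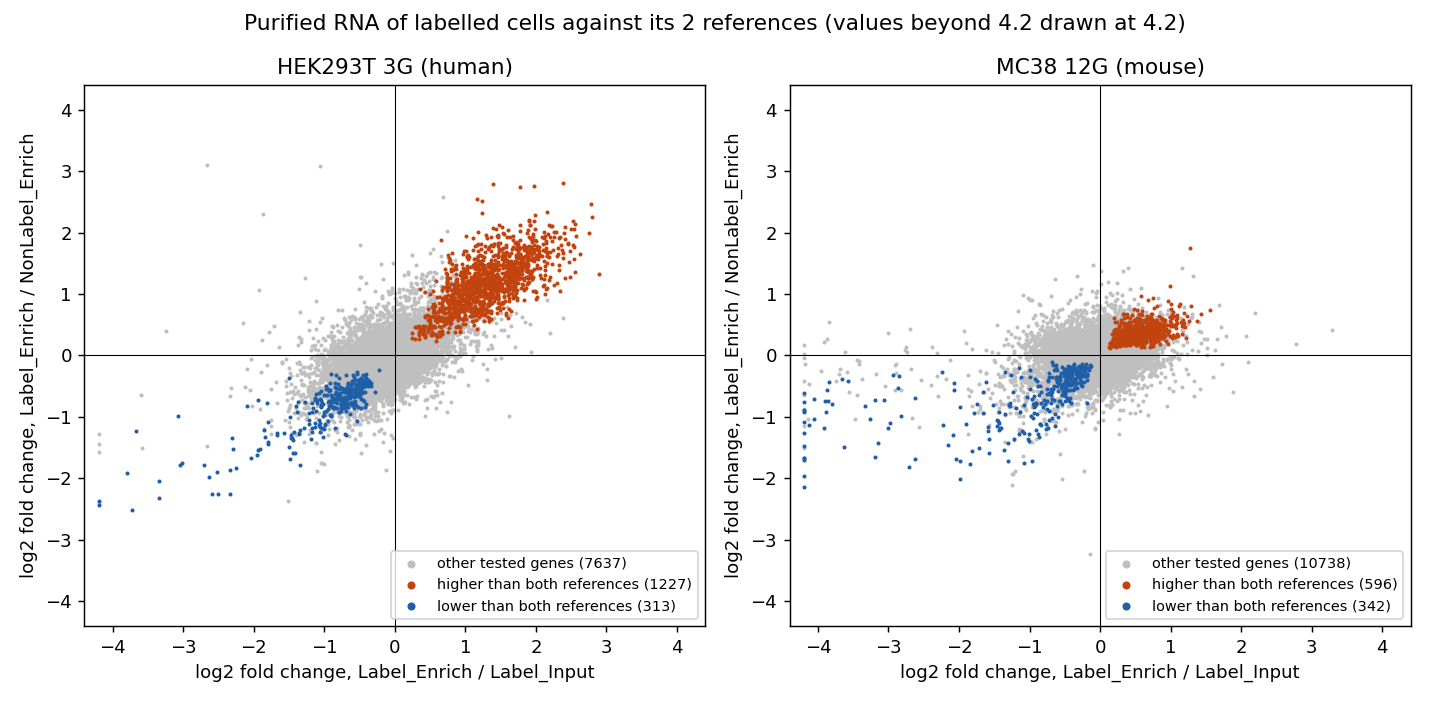
Log2 fold change against Label_Input (horizontal) and against NonLabel_Enrich (vertical), with 1 point per tested gene in HEK293T 3G and MC38 12G and values beyond 4.2 drawn at 4.2. Genes higher than both references numbered 1227 in HEK293T 3G and 596 in MC38 12G.

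The MC38 3G counts were compared with MC38 12G as a shallower count of the same libraries. Of the genes named by size in MC38 12G, 6 of 8 higher and 8 of 8 lower were also named in 3G against Label_Input, and 7 of 8 in each direction against NonLabel_Enrich. In the second case, Vcam1, an adhesion molecule, and Errfi1 took the other places. Col4a1 stood at 77.7 ± 1.55 CPM in Label_Enrich and 29.0 ± 2.76 CPM in Label_Input (SD, n = 3), and Egr1 at 69.8 ± 1.37 CPM in Label_Enrich and 167 ± 6.89 CPM in NonLabel_Enrich. List calls had the same result and direction in 20 of 22 tested lists against Label_Input (the translocon and the integrated stress lists differed), in 21 of 22 against NonLabel_Enrich (the cytoskeleton list differed) and in 22 of 22 for NonLabel_Enrich against Label_Input. edgeR called 2733 of 11005 genes against Label_Input (1326 higher, 1407 lower, or 1825 and 993 without the low-count filter), 1849 against NonLabel_Enrich (969 and 880, or 1025 and 598) and 2776 for NonLabel_Enrich against Label_Input (1346 and 1430, or 1650 and 1044). Called in both depths with the same sign were 2546, 1704 and 2573 genes, and with opposite signs 0 in each comparison. Above both references lay 483 genes, where independent lists would share 116.8. Simulations with unchanged groups called 0.05 genes on average against Label_Input, so their 0 genes in both is no yardstick here. The covariance was 0.0609 against 0.0137 simulated.

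In HEK293T 3G, ENSG00000123146 and ENSG00000168216 had the largest rises from Label_Input to Label_Enrich among IDs that met the conditions for HEK293T. ENSG00000123146 rose from 5.83 ± 2.18 to 38.4 ± 13.9 CPM (SD, n = 3; log2 fold change 2.796 ± 0.45 SE, edgeR adjusted p = 4.10e-07), and ENSG00000168216 from 6.82 ± 4.16 to 51.6 ± 2.73 CPM (2.75 ± 0.39, edgeR adjusted p = 1.30e-08). ENSG00000199347 stood at 2.18 ± 2.41 CPM in Label_Enrich and 50.4 ± 1.10 CPM in Label_Input (-4.32 ± 0.47, edgeR adjusted p = 3.64e-12). ENSG00000278233 stood at 14.9 ± 4.97 and 451 ± 680 CPM (-4.96 ± 0.51, edgeR adjusted p = 3.08e-13); Label_Input replicate 2 decides this size, and without it the log2 fold change was -1.99 (edgeR adjusted p = 1.33e-05, range over the alternatives 2.49e-158 to 0.000369). The edgeR test called 2664 of 9177 genes, 1567 higher and 1097 lower in Label_Enrich, of which 981 and 300 differed at least 2-fold, and groups did not overlap in 40.2% of tested genes against 10% by chance. Without the low-count filter the split was 1651 higher and 705 lower.

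Against NonLabel_Enrich, the same IDs gave 2.26 ± 0.38 for ENSG00000123146 and 2.00 ± 0.32 for ENSG00000168216, and -1.27 (edgeR adjusted p = 0.265) for ENSG00000278233 and -1.57 (edgeR adjusted p = 0.0846) for ENSG00000199347. Of 9177 HEK293T genes, 2133 were called by edgeR, 1460 higher and 673 lower in Label_Enrich, of which 914 and 124 differed at least 2-fold, and groups did not overlap in 35.1% of tested genes against 10% by chance. NonLabel_Enrich against Label_Input gave 642 calls, 272 higher and 370 lower, with 23 and 127 at least 2-fold; the DESeq2 Wald test gave 375 calls, leaving out Label_Input replicate 2 gave 395, and without the low-count filter the split was 322 higher and 271 lower.

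Above both references in HEK293T 3G lay 1227 genes, ENSG00000123146 and ENSG00000168216 among them, and 313 lay below both, while 27 had opposite calls. Independent lists of these sizes would share 249.3 higher and 80.4 lower genes. Simulations gave 0 genes higher in both, but with 0.05 genes called on average against Label_Input they are no yardstick for the 1227. The covariance of the fold changes was 0.345, against 0.0301 simulated. At least 2-fold above both lay 733 genes. The Label_Enrich libraries are shared here too. At the HEK293T depth of 442059 to 1135243 counts per library, 21.0% of simulated 1.5-fold changes against Label_Input were recovered. That simulation changed 200 of 9177 genes, where the data gave 2664 calls, and used the spread of HEK293T. Recovery in the data may therefore differ, and an effect of depth alone on this recovery was not tested.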

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

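Removal of features holding over 1% of a library was chosen after seeing the data, while the other alternatives here were planned. Of 197 counts of called genes under an alternative, 177 stayed within 1.5 times the reported count and 20 moved further. Similar counts can hold different genes. In MC38 12G against Label_Input, RLE factors kept 97.9% of the reported calls, but no low-count filter, with 3405 calls, kept 79.5%. Leaving out Label_Input replicate 2 kept 74.4% in HEK293T against Label_Input. Leaving out Label_Enrich replicate 1 kept 70.7% in MC38 3G against NonLabel_Enrich. Over the MC38 comparisons of Label_Enrich, gene list calls were rerun only with an estimated correlation, with fry, and with a replicate block in camera. Both MC38 sets, which hold the same libraries, were counted. List calls kept their side of the threshold in 231 of 264 cases, gained a call in 9 and lost it in 24. Named genes kept their side in 3765 of 3839 cases, gained a call in 32 and lost it in 42. Directions were compared only where a call was made, and 0 named genes or lists were called in the opposite direction in these comparisons. For NonLabel_Enrich against Label_Input, where only the estimated correlation is given here, lists went from 3 called higher and 8 lower to 3 and 5 in each MC38 set. Among all genes, 1 HEK293T gene called against Label_Input was called in the opposite direction without Label_Enrich replicate 1.

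A minimum fold of 2 keeps fewer genes by construction. It left 1281 HEK293T genes against Label_Input, 1038 against NonLabel_Enrich, 150 for NonLabel_Enrich against Label_Input and 733 above both. In MC38 12G it left 361, 111, 327 and 1, and in MC38 3G 321, 94, 300 and 0. An adjusted p under 0.01 left 347 for NonLabel_Enrich against Label_Input in HEK293T, 1468 in MC38 12G and 1061 in MC38 3G for Label_Enrich against NonLabel_Enrich, and 1778 in MC38 3G for NonLabel_Enrich against Label_Input. The DESeq2 Wald test gave 375, 1512 and 1075 calls for the first 3 of these. On simulated 2-fold changes against NonLabel_Enrich, it recovered 52% in HEK293T, 84.5% in MC38 12G and 82% in MC38 3G. On the same counts edgeR recovered 67%, 90% and 88.5%. False calls were 0%, 0% and 0.606% with DESeq2, and 2.19%, 4.26% and 2.21% with edgeR. DESeq2 thus called fewer true changes there, while NonLabel_Enrich against Label_Input was not simulated. With an estimated correlation, 9 lists in MC38 12G against Label_Input (18 before) and 11 in MC38 3G against NonLabel_Enrich (17 before) were called, and the cause was not tested.

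With each library left out in turn, and so with fewer samples, HEK293T gave 2126 to 2402 calls against Label_Input, 1733 to 1936 against NonLabel_Enrich, 395 to 497 for NonLabel_Enrich against Label_Input, and 1054 to 1168 genes above both. The 395 came without Label_Input replicate 2. MC38 12G gave 2763 to 3026, 1819 to 2029, 2843 to 3242 and 494 to 573, and MC38 3G 2217 to 2420, 1371 to 1537, 2182 to 2654 and 389 to 446. With a replicate block, HEK293T gave 2621, 2101 and 615 calls, MC38 12G 3346, 2375 and 3432, and MC38 3G 2667, 1791 and 2715. Equal replicate numbers were not treated as pairs, since in no comparison were all 3 correlations of same-numbered libraries above 0.1. In MC38 3G, Label_Enrich against NonLabel_Enrich, they were 0.212, 0.0489 and 0.122, and all 3 libraries correlated best with their own number. In MC38 12G they were 0.258, -0.00902 and 0.0134, and 1 library correlated best with its own number. The 3G result is a hint from the data and not from the design, and the deeper counts did not repeat it. Without features over 1% of a library, MC38 12G gave 3435, 2354 and 3471 calls. Removal of mitochondrially encoded genes was not run for HEK293T, whose features had no names here, and tests of differences between cell lines or between MC38 sets were not run.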

Other observations

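The 3 patterns below were picked after fold changes were seen, and the criteria of their tests were written before each test was run. For immediate early genes the tested values are list medians already given above, so those criteria cannot count as set in advance. The look at Filip1l and the length check of gene lists were chosen after their values were seen. In MC38 12G, the 1585 genes whose longest protein starts with a hydrophobic stretch, as signal peptides do, had a median log2 fold change of 0.17 in Label_Enrich against NonLabel_Enrich, with 487 higher and 56 lower. The 7008 genes with no hydrophobic segment had -0.02, with 446 higher and 789 lower, and 1911 genes with an internal segment had 0.03. The difference of 0.20 between the first 2 medians had a permutation p of 1e-05, the smallest that 100000 permutations can give. Genes are not independent, so this p covers the shuffling of genes and not new samples. After removal of the trend on transcript length 100.05% of the difference was left, and 101.05% after the trend on GC share, which argues against either trend as its whole source. A candidate explanation is that RNAs translated at the ER were labelled more. No group with an enzyme placed elsewhere was part of the design to test it further. The internal class, with 248 higher and 141 lower, lay nearer to the class without a segment. Lists outside the ER and secretory pathway are not addressed by it. Some of them, such as histones and proteasome, also had medians above 0 here, and others, such as cytoskeleton, below 0.

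Immediate early genes such as Egr1, Dusp1 and Ier2 had a median of -1.19 in Label_Enrich against NonLabel_Enrich. The same list stood at -0.86 against Label_Input, which puts these RNAs lower after capture within labelled cells. That value and the one of NonLabel_Enrich against Label_Input nearly add up to the pattern by construction, so they divide it and are not separate tests of a loss on purification. In NonLabel_Enrich against Label_Input the list stood at 0.31, under 50% of the size of -1.19, the bound set for a higher level in the unlabelled cells. As written, the criterion counted a value under that bound against a higher level. The value does not settle the matter, since NonLabel_Enrich was captured and Label_Input was not. No RNA of unlabelled cells before capture was sequenced, so capture and culture cannot be told apart for this list.

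The 95th percentile of the absolute log2 fold change against NonLabel_Enrich was 1.45 in HEK293T 3G and 0.48 in MC38 12G, over genes with a mean count of at least 50. After MC38 counts were thinned to the HEK293T depth outside their most abundant feature, the MC38 percentile was 0.55, or 37.6% of the HEK293T value, and it was 42.1% after thinning of the whole library. This argues against depth as the whole source of the difference. The cell line, its enzyme level and the labelling itself stay open, and a biological explanation was not tested.

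The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05. In each of the 9 comparisons 1 of 10 splits, the real one, gave as many calls, and the highest other split gave 0. The real splits gave 2599, 2159 and 644 calls in HEK293T 3G, 3412, 2460 and 3243 in MC38 12G, and 2789, 1891 and 2638 in MC38 3G, in the order Label_Enrich against Label_Input, Label_Enrich against NonLabel_Enrich, and NonLabel_Enrich against Label_Input.

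Filip1l stood at 299 CPM in NonLabel_Enrich replicate 2 of MC38 12G and at 11.3 and 12.0 CPM in the other NonLabel_Enrich libraries. Its values in the other groups ran from 11.1 to 12.9 CPM.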
